A study of Homo sapiens with 48 samples.

How the data were processed

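Open chromatin was measured by ATAC-seq in 48 libraries of untreated breast cancer cell lines. Per the labels' protocols, 50000 sorted nuclei per library were cut with Nextera transposase after growth in RPMI with serum to near confluence, and the libraries were size selected. Per the submitters' processing notes, reads were aligned to hg38 with Bowtie2 2.05, handled with SAMtools 0.1.18, and peaks were called with MACS2, whose version is not given. The deposited lists hold one peak per line, and their names mark them as filtered and merged by the authors. How they were filtered and merged, whether reads were shifted for the transposase and whether duplicates were removed is not given in the labels or the lists. The deposited score is a whole number that equals 10 times the -log10 q, cut to a whole number. The authors' fold enrichment is a ratio of each peak to the peak caller's local background in the same library. The remaining deposited columns hold -log10 p and -log10 q, the latter adjusted within the library by the peak caller. None of these was rescaled between libraries, so fold enrichment was used only as a rank within a library, and its 99th percentile was compared as a description. Read depth is unknown, and the number of deposited peaks was used in its place, so a region without a peak was not detectable in that library rather than shown to be closed.

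Line, subtype and replicate number came from the labels. The spellings HS-578-T and HS578, MDA468 and MDA-MB-468, and SUM149 and SUM149PT were each joined as 1 line. Peak midpoints from all libraries were reduced to regions of 501 bp that do not overlap, taken in order of their rank by fold enrichment, on the autosomes and chromosome X, and chromosome Y was left out. A region was open in a library if a peak overlapped it by at least 1 bp, and regions open in fewer than 2 libraries were dropped. A region was open in a line if open in at least 1 of 2 or 2 of 3 libraries. Regions were assigned to the nearest protein-coding gene span within 100 kb from RefSeq on GRCh38, whose coordinates are those of hg38. All 339 listed symbols matched, and 338 were used at gene ends. The log2 of open regions plus 0.5 was analysed for genes with at least 1 open region on average.

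The comparisons and their tests were fixed before the data were examined. They were similarity between libraries (Jaccard index at 65188 top peaks each, 100000 permutations), Luminal A against TNBC lines (exact permutation over 276 pairs of lines), the unnumbered against the numbered library of 5 lines (exact sign flips), regions open in both Luminal A lines only, and gene ends of listed genes (Fisher's exact test). Genes were compared with limma 3.58.1 in R 4.3.3, by subtype on line means with peak number as a covariate, and between 19 TNBC lines on 38 libraries by the moderated F test. The 14 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, and list spreads were ranked among 10000 random lists. Correlations used 100000 permutations, or all orderings under 10 lines. The false discovery rate was held at 0.05 by Benjamini-Hochberg adjustment. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

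The genes named by subtype were to be the 12 largest each way past adjustment and up to 4 past adjustment per list, together with ESR1, GATA3, FOXA1, KRT5, TP63, VIM, ZEB1 and CDH1 whatever their values. Between lines they were the 15 with the largest SD and up to 3 of the largest per list, at gene ends up to 3 of the largest difference per list, and among regions the 10 with the highest mean rank of fold enrichment. Genes outside this rule are said to have been named after their values were seen.

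Several planned steps were changed because genome sequence and strand were not used here. Distance to the gene span replaced distance to the start site, either end of the gene (within 1 kb) replaced the promoter, and the midpoint of a peak replaced its summit. Start sites inside a gene span were therefore not covered at gene ends. The 19 motif tests and the 7 of 8 relations that needed motifs were not run, and exons and introns were not told apart. For peak number, equal top peaks fix the value in each library, so that alternative was not used there.

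The limma fits were tested on 3 simulated data sets, and the overlap and permutation steps on simulated values. In the comparison by subtype over 17194 genes with a spread between lines of 0.4, limma called 0 of 300 genes changed 2-fold and 60 of 300 changed 4-fold, and 59 of 50982 unchanged genes. With a spread of 0.1 it called 51, 285 and 213. Because of these false calls and the count of 0 in the data, a fit of single libraries with the line as a block and a fit of lines weighted by their libraries were added after the result was seen. At a spread of 0.4 the block fit called 1 of 300, 20 of 300 and 7 unchanged genes, and the weighted fit 0, 0 and 2, and at 0.1 they called 9, 211 and 20, and 1, 170 and 11. A mean-variance trend was tried on simulated data only and not used. The F test over 16507 genes called 0 of 300 genes raised 2-fold or 4-fold in 1 line, with 0 unchanged genes called. It can thus miss a gene raised by that much in a single line. For genes raised in 10 of 19 lines it called 12 of 300 at 2-fold, 285 of 300 at 4-fold and 27 of 48921 unchanged genes. These simulations changed 200 genes, whereas 15410 passed in the data, where adjustment was therefore far less strict. The simulated counts thus give neither the sensitivity nor the false calls of the count in the data. An unadjusted p of the F test under 0.05 was found for 52.3% of genes raised 4-fold in 1 line. It was found for 8.67% of those raised 2-fold and 5.29% of unchanged genes.

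There were 66 alternatives planned beforehand and 25 chosen after the data were seen. They covered the choice of peaks, the q-value, the overlap, the distance to a gene, the pseudocount, the filter, the covariate, the sets of libraries, joined names and left-out libraries. Those added include the results without the library labelled SUM149PT replicate 2, list levels per line in 6 settings, 15 pairs of lists, and Luminal A regions by list. The tests of wide peaks and of windows without peaks were also added after the data were seen.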

Results

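Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts open DNA, in 48 libraries of untreated breast cancer cell lines. The series concerns triple-negative breast cancer (TNBC, tumours that lack hormone receptors and HER2 amplification), and its title ties open chromatin and transcription factor networks to prognosis and to how tumours respond to drugs. After spellings of 3 line names were joined, the libraries covered 24 lines. Of these, 22 were labelled TNBC, and MCF7 and T47D, both oestrogen receptor-positive lines, were labelled Luminal A. A replicate number stood in the titles of 38 libraries, a pair from each of 19 TNBC lines. The other 10 libraries had no number and came from 8 TNBC lines and both Luminal A lines, with 1 library per line, and 5 lines were in both sets. The labels do not say that replicates were separate cultures, so p-values that rest on replicates measure the spread between these libraries, whether technical or biological. Read depth was unknown. The deposited lists held from 65188 peaks in MDA-MB-436 replicate 2 to 256763 in HBL100, with a median of 136112. Together they gave 648071 regions of 501 bp that were open in at least 2 libraries on the hg38 build. Of these, 336165 lay inside the span of a protein-coding gene, and 543986 lay inside or within 100 kb of one. Of the 648071 regions, 13421 were open in all 24 lines. Of the 644127 among them that were open in any line, 88872 (13.8%) were open in a single line. Candidates open in 1 library only had been dropped before (from 915073 candidates), so this share is lower than over all candidates.

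Open chromatin separated the lines from each other. Among the 43 libraries that had another library of the same line, 39 were nearest to their own line by the shared fraction of regions (Jaccard index) at 65188 top peaks each, and a one-sided permutation of the line labels gave p = 1e-05, the smallest value it allows. Numbered libraries of one line had a median index of 0.619 (range 0.344 to 0.800, 19 pairs), against 0.304 for libraries of different lines. MDA-MB-231, a mesenchymal-like line, had the closest pair. MCF7 and T47D were each other's nearest library (0.513). The exceptions were the unnumbered HCC1806 library, nearest to HDQP-1 at 0.522 and to its own line at 0.511, and all 3 SUM149 libraries. Of these, the unnumbered library was nearest to HDQP-1 (0.502) and SUM149PT replicate 1 to CAL85-1 replicate 2 (0.482). The index between these 2 SUM149 libraries was 0.451. The library labelled SUM149PT replicate 2 was nearest to both SUM159PT libraries (0.549 and 0.550) and had an index of 0.344 with SUM149PT replicate 1. It is called by its label throughout, and the counts of nearest libraries, Luminal A regions, genes, lists and gene ends were also obtained without it.

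MCF7 and T47D had 194075 ± 1411 peaks (SD, n = 2 lines) and the TNBC lines 139352 ± 39802 (SD, n = 22). An exact two-sided permutation over the 276 pairs of lines gave p = 0.0725, so the difference was within the spread between lines. With peaks at a q-value of at most 1e-05 the exact permutation p was 0.0254, and among unnumbered libraries alone it was 0.4, with a difference of 22290 peaks. Peaks within 1 kb of either end of a protein-coding gene made up 12.6 ± 0.672% in the Luminal A lines and 15.7 ± 2.97% in the TNBC lines (exact permutation p = 0.145). With equal numbers of top peaks the direction turned, at 21.6% against 20.6% (exact permutation p = 0.489).

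Both Luminal A lines lay in the unnumbered set, which differed from the numbered set as a whole. In the 5 lines with both, HCC1806, HCC3153, HS578, MDA-MB-468 and SUM149PT, the unnumbered library held 45864 ± 41250 more peaks (SD) and was higher in 5 of 5. An exact two-sided sign-flip permutation gave p = 0.0625, the smallest that 5 lines allow. The 99th percentile of the authors' fold enrichment was 4.39 times as high in the unnumbered libraries of these lines, also in 5 of 5. Without the library labelled SUM149PT replicate 2, the peak number was higher in 4 of 5 lines and the exact permutation p was 0.188. Subtype and set were thus confounded in part in each comparison of Luminal A with TNBC that uses all libraries.

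**Figure D1:**
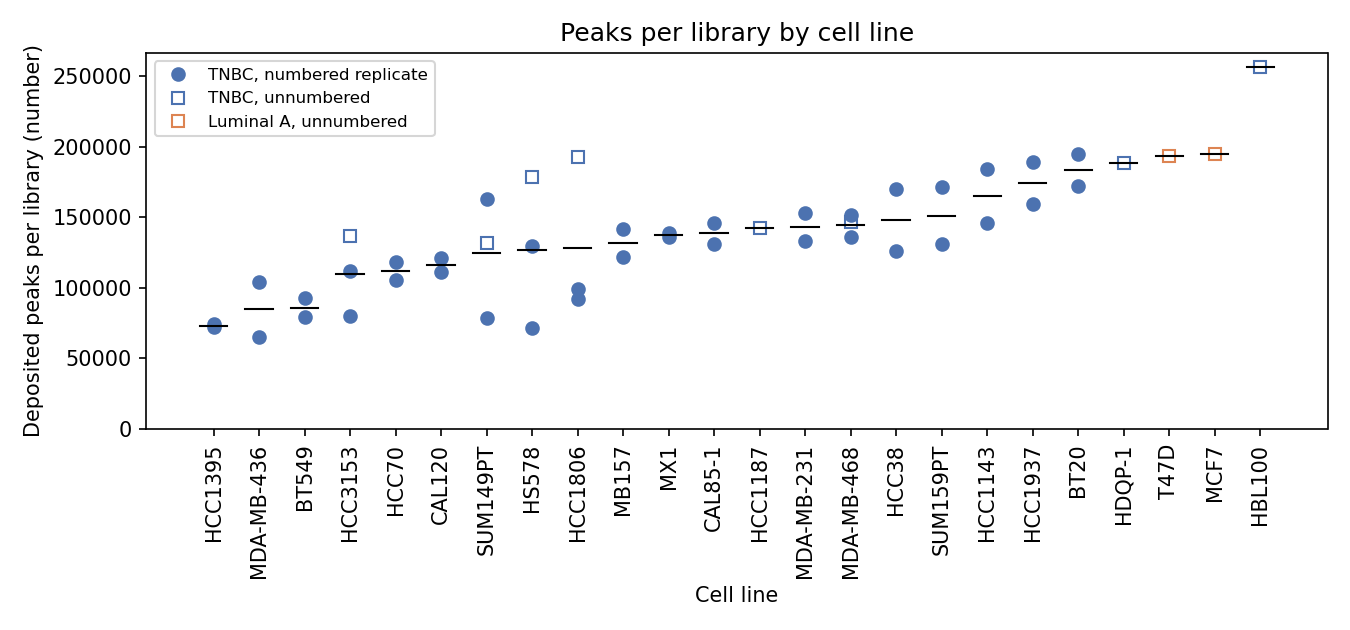
Deposited peaks per library (y axis, number) for each of the 24 cell lines (x axis). Filled circles are numbered TNBC libraries, open squares unnumbered libraries, colour gives the subtype, and the bar is the mean of the line. MCF7 and T47D hold 195073 and 193077 peaks, and the TNBC line means run from 73161 to 256763.

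MCF7 and T47D shared 6445 regions that were open in no TNBC line, out of 132711 regions open in both. Across the 276 pairs of lines the median count of such regions was 267.5, and 1 other pair, HBL100 with MX1, was higher at 7798 (exact permutation p = 0.00725). By the rank of the authors' fold enrichment, the leading such region lay at chr14:75258036-75258536, 20542 bp from FOS, an AP-1 subunit. The next lay at chr2:237559870-237560370, 4798 bp from MLPH, which encodes melanophilin. Others of the leading 10 lay inside the spans of HTT (chr4:3112074-3112574), DSCAM (chr21:40382722-40383222), CCDC88C (chr14:91276307-91276807), GINS2 (chr16:85681184-85681684) and WDR20 (chr14:102185384-102185884). The remaining 3 lay outside the nearest gene, at chr7:128431675-128432175 near IMPDH1, chr2:189542474-189542974 near the iron exporter gene SLC40A1, and chr12:116503788-116504288 near MAP1LC3B2. Whether those inside a gene lay in an exon or an intron was not analysed here. Among the unnumbered libraries alone the count was 10507, the highest of 45 pairs (exact permutation p = 0.0222). It was 2474 with equal numbers of top peaks, where 2 other pairs were as high (exact permutation p = 0.0109), and 11109 for regions open in every library of a line (exact permutation p = 0.00362, the smallest possible). That last rule favours lines with 1 library, as MCF7 and T47D are. The next highest pair under it, HBL100 with T47D at 6950, also had 1 library per line.

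No gene had a number of open regions that differed between Luminal A and TNBC lines past an adjusted p of 0.05 (0 of 17194, limma with Benjamini-Hochberg adjustment), and 869 had an unadjusted p under 0.05. That count is close to the share of 0.05 that no difference would give. On simulated data the same fit put 7.58% of unchanged genes under it at a spread of 0.4, and 8.14% at 0.1. Log2 differences are given as Luminal A minus TNBC with peak number as a covariate, and their median over all genes was 0.24. ESR1, the oestrogen receptor gene (chr6:151656672-152129619), lay near 53 ± 2.83 open regions (SD, n = 2) in Luminal A and 20.3 ± 8.75 (SD, n = 22) in TNBC lines, a log2 difference of 0.95 ± 0.63 (SE). GATA3 (chr10:8045333-8075198), a luminal transcription factor, had 55.5 ± 4.95 against 17 ± 11.6 regions, a difference of 1.15 ± 0.82. The pioneer factor gene FOXA1 (chr14:37589552-37595249) had 16.5 ± 0.707 against 6.06 ± 2.63, a difference of 1.20 ± 0.44. For CDH1, which encodes E-cadherin (chr16:68737292-68835537), the log2 difference was 0.28 ± 0.97. Basal markers gave 0.33 ± 0.87 for KRT5 (chr12:52514575-52520394) and -0.08 ± 0.52 for TP63 (chr3:189596746-189897276). Mesenchymal markers gave -0.52 ± 0.46 for VIM (chr10:17228241-17237593) and -0.53 ± 0.49 for ZEB1 (chr10:31318417-31529804). None of these 8 genes passed adjustment, and the sign for KRT5, TP63, VIM and ZEB1 turned in at least 1 other setting each. The count of genes past the threshold was 39 with equal numbers of top peaks, 59 with no filter on low counts, 9 with the stricter q-value and 6 with the peak required to cover the region's centre. It was 3 within 10 kb (TMEM200C, TINAG, CHST2), 2 with line names kept apart (GUCY1A1, GKN1) and 1 without the T47D library (CNN3), each lower in Luminal A. Fitting single libraries with the line as a correlated block gave GABRE, ZFP42 and GKN1, also lower, and fitting lines weighted by their libraries gave 0. These genes were named after their values were seen, and on simulated data this comparison also called unchanged genes.

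**Figure D2:**
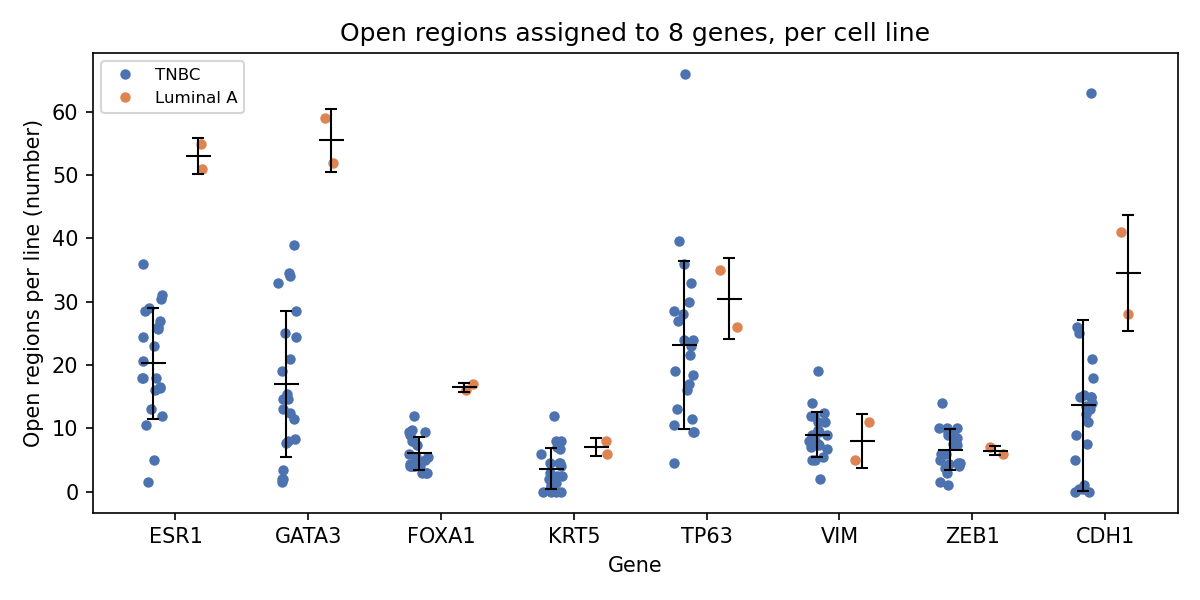
Open regions assigned to 8 genes fixed in advance (y axis, number per line; x axis, gene). Each point is a cell line, blue for TNBC (22 lines) and orange for Luminal A (2 lines), and black bars are the mean and SD. ESR1 lies at 51 and 55 in MCF7 and T47D and at most at 36 in the TNBC lines.

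Genes of the luminal and hormone receptor list lay near more open regions in the Luminal A lines as a group. Of its 30 genes, 28 had a log2 difference above the median of all genes, and in 11 both Luminal A lines were above each TNBC line. Were the lines exchangeable, 1 of 276 splits would give this per gene. However, the Luminal A lines held more peaks on average and were both unnumbered, so the true rate may be higher. In each other list at most 1 gene met this condition. The list's median difference was 1.11 (camera of limma with a preset correlation, adjusted p = 4.52e-08; adjusted p = 0.0266 with an estimated correlation). Adjusted over the list alone, 3 genes passed and were higher, against 0 over all genes. These were TFF1 and GREB1, which oestrogen induces in breast cells, and the stress response factor gene XBP1, with log2 differences of 2.40 ± 0.56, 2.76 ± 0.75 and 1.92 ± 0.59 (SE), named after their values were seen. GREB1 lay near 86.5 ± 12 open regions in Luminal A and 10.2 ± 5.81 in TNBC lines. The call with an estimated correlation was lost in 3 of 16 other settings: no filter, no covariate, and T47D left out. A test of list levels per line, chosen after the data were seen, placed both Luminal A lines above 22 of 22 TNBC lines relative to all genes (exact permutation p = 0.00362, adjusted over 14 lists 0.0254). Within the unnumbered libraries alone they were above 8 of 8 (exact permutation p = 0.0222, the smallest possible, adjusted 0.0622). There the hepatocyte list was likewise higher (0.68), and the AP-1 and YAP/TEAD (-0.53), basal (-0.57) and luminal progenitor (-0.51) lists lower, than in 8 of 8 TNBC lines with the same p, against 1.06 for the luminal list.

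The basal and myoepithelial list and the mesenchymal list ran the other way relative to all genes. Of 28 basal genes 23 were at or below the median of all genes, with a list median of -0.16 (camera adjusted p = 3.27e-04; adjusted p = 0.223 with an estimated correlation). Among them were DSC3 at -2.86 ± 0.86 and SOX10 at -2.44 ± 0.95 (SE). Of 30 mesenchymal genes 24 were at or below that median, with a list median of -0.23 (camera adjusted p = 3.27e-04; adjusted p = 0.287 with an estimated correlation), among them CAV1 at -1.53 ± 0.54. These 3 genes were chosen after their values were seen. Neither call held with an estimated correlation in any setting, and adjusted over the list alone 0 genes of either list passed. The basal call was also lost with equal numbers of top peaks (limma camera adjusted p = 0.370) and with counts scaled by peak number (0.109).

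The other 11 lists did not pass camera. The hepatocyte list had a median of 0.90 (camera adjusted p = 0.0559; adjusted p = 0.287 with an estimated correlation), and 2 of its 15 tested genes, TAT and HNF1A, passed adjusted over the list alone. It passed in 7 of 16 other settings with the preset correlation and in none with an estimated one. CCNB1 of the cell cycle list and POLR2A of the housekeeping list also passed adjusted over the list alone, and all 4 genes were named after their values were seen. Camera adjusted p-values were 0.128 for housekeeping, 0.146 for homologous recombination repair, 0.188 for the AP-1 and YAP/TEAD programme and 0.835 for luminal progenitor genes. They were 0.856 for the epithelial, interferon and antigen presentation, and endothelial lists, 0.865 for drug transport and metabolism, and 0.911 for cell cycle and for immune cells. The AP-1 and YAP/TEAD list had a median of 0.03 and a mean of -0.03. Camera placed the luminal progenitor, epithelial, interferon, cell cycle and endothelial lists below the other genes although their medians and means were above 0, and the endothelial and luminal progenitor medians of 0.35 and 0.32 were above that of all genes.

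At the ends of the listed genes, 0 of 338 differed between subtypes past adjustment (Fisher's exact test with Benjamini-Hochberg adjustment). With 2 against 22 lines the smallest possible p of Fisher's exact test is 0.00362. It passes adjustment over 338 genes only if many genes reach it, so this 0 says little about single genes. An unadjusted p under 0.05 was found for 3 genes. These were TP63, open at an end in 2 of 2 Luminal A and 1 of 22 TNBC lines, the gluconeogenic gene G6PC1 with the same counts, and the leukocyte gene PTPRC in 2 of 2 and 3 of 22, named after their values were seen. An end of ESR1 was open in MCF7, but not in T47D or in any of the 22 TNBC lines. Only the outer ends of each gene span were examined, so start sites inside a span were missed. A gene end with or without a peak therefore does not show whether a promoter was open. Ends of FOXA1 were open in all 22 TNBC lines, of GATA3 in 14, of CDH1 in 15 and of AGR3, a luminal gene, in 4, and each was open in both Luminal A lines. DSC3, CCND2, CDH5, SPARC, PROM1 and IFI44L were open at an end in 15, 12, 16, 14, 13 and 12 TNBC lines respectively and in neither Luminal A line. By list, 95.0% of luminal genes had an open end in the Luminal A lines and 71.2 ± 11.3% in TNBC lines (SD, n = 22). Epithelial genes stood at 100% and 84.3 ± 22.9%, with HS578 lowest at 32.1%, and mesenchymal genes at 78.3% and 77.7 ± 8.44%. Basal genes stood at 76.8% and 67.9 ± 14.8%, so their share was higher in Luminal A, and housekeeping genes at 100% and 99.8 ± 0.888%. Hepatocyte genes stood at 52.5% and 36.1 ± 12%, and immune genes at 65.9% and 48.3 ± 11%. The share was higher in Luminal A for each of the 14 lists, and these shares were not tested. They used all deposited peaks, and the Luminal A lines held more peaks on average and were both unnumbered. Peak number and set can therefore not be told apart from subtype in these shares.

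Between the 19 TNBC lines with numbered replicates, most genes differed by more than their replicates did (15410 of 16507, 93.4%, limma moderated F test with Benjamini-Hochberg adjustment). In the labels, both of these libraries of a line carry the same style of library index. A difference in preparation that followed the style would therefore count as a difference between lines. The number of open regions near epithelial regulators varied widely, and whether the copy number of a locus contributed was not tested. GRHL2 (chr8:101492439-101681200), an epithelial transcription factor, lay near 113.5 open regions in HCC1143, 90 in HCC1937, 72.5 in MB157 and 0 in MDA-MB-436. CDH1 lay near 63 in BT20, 21 in HCC1937, 0.5 in BT549 and CAL120 and 0 in HCC1395 and MDA-MB-436. EHF (chr11:34621093-34663288) and ELF5 (chr11:34478791-34513794), neighbouring ETS factor genes, peaked in HCC1806 at 105 and 79 and in MDA-MB-468 at 53 and 28, with medians over lines of 9.5 and 3.5. The nearby CD44 was at 144.5 and 70.5 in the same lines. KRT17, a basal keratin, ranged from 0 to 22.5, the laminin gene LAMA3 from 1 to 79, and the mesenchymal-associated factor TCF4 from 0 in HCC1937 and HCC70 to 23.5 in MX1. The androgen receptor gene AR was at 0 in CAL120, HCC1395, HCC1937 and MDA-MB-468 and at 11.5 in MDA-MB-231. CDKN2A (chr9:21967752-21995324), a cell cycle inhibitor gene, was at 0 in BT20, HCC1806, HCC38, MDA-MB-231, SUM149PT and SUM159PT and at 10.0 in HCC70, and its neighbour CDKN2B was at 0 in HCC38 and MDA-MB-231. Values are means of 2 libraries, and those of SUM149PT include the library labelled replicate 2.

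By list, the share that differed between lines was 28 of 28 tested luminal, 27 of 27 basal, 26 of 27 epithelial, 30 of 30 mesenchymal and 14 of 15 luminal progenitor genes. Adjusted over the list alone, the counts were 28, 27, 26, 30 and 15. The remaining lists gave 24 of 25 AP-1 and YAP/TEAD, 22 of 23 interferon, 23 of 25 homologous recombination, 19 of 21 drug transport, 23 of 24 cell cycle, 22 of 24 housekeeping, 16 of 17 immune, 16 of 16 endothelial and 13 of 13 hepatocyte genes, and the same counts adjusted over the list alone. The size of the variation differed between lists. The median SD between line means was 1.12 (log2) for basal and 1.07 for epithelial genes, at percentiles 98.4 and 97.2 of 10000 random lists matched on level, against 0.58 for housekeeping genes (percentile 0.04) and 0.64 for homologous recombination genes (2.70). Luminal, luminal progenitor, hepatocyte and endothelial lists stood at percentiles 94.7, 97.6, 97.1 and 99. The mesenchymal list stood at 56.0, immune at 68.7, drug transport at 27.8, interferon at 19.1, cell cycle at 14.1 and AP-1 and YAP/TEAD at 1.34. Named as examples of these lists, SLFN11, a gene of the DNA damage response, ranged from 0 to 7 open regions, the interferon-induced OAS2 from 0 to 6 and the drug-metabolizing CDA from 0 to 10.0.

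The largest SD between lines belonged to genes outside the lists, several of which were neighbours. CFAP46 (chr10:132808392-132942570), ADGRA1 (chr10:133087924-133131675) and TCERG1L (chr10:131092391-131311721) lay near 190.5, 143 and 160.5 open regions in MDA-MB-436 and 185.5, 139.5 and 155 in HCC1937. CFAP46 and ADGRA1 were also high in HCC38, at 152.5 and 111.5, where TCERG1L was at 0. Both were also above their medians in SUM159PT, CFAP46 at 58.5. Their medians over lines were 3.5, 5.5 and 1.5. On chromosome 19, ZNF536 was highest in HCC1395 at 201 and its neighbour VSTM2B in MB157 at 160.0. UNCX and ELFN1 on chromosome 7 were highest in HCC1937 at 93.5 and 110.0, and LOC112268384 on the same chromosome in SUM159PT at 69.5. PTPRD, a phosphatase gene (chr9:8314246-10613002), lay near 355.5 open regions in HCC38 and 0 in HCC1143 and HCC1395. The other members of the leading 15 were TAS2R1, PTPRT, FAM135B, EDN3, B3GAT1 and ZNF716.

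The last question was whether TNBC lines with more open chromatin near epithelial genes had less near mesenchymal genes. With equal numbers of top peaks, Pearson's r between the list levels was -0.26 over 22 lines (permutation p = 0.232) and Spearman's rho was -0.34 (permutation p = 0.124), so no relation was shown over the pooled lines. It was the 1 of 8 fixed relations that could be computed, so its adjusted p equals its raw p, and among 15 pairs of lists added later it was 0.295. Without the lines farthest on the epithelial axis, HBL100 and MDA-MB-436, r was -0.40 (permutation p = 0.0840) and rho -0.48 (permutation p = 0.0337). Pooling joined numbered and unnumbered libraries, and the values differed by set. Within the 10 numbered lines with index numbers r was -0.50 (permutation p = 0.135) and rho -0.68 (permutation p = 0.0344). Within the 8 unnumbered TNBC libraries r was -0.69 (exact permutation p = 0.00742) and rho -0.71 (exact permutation p = 0.0576). Both within-set values were chosen after the data were seen and are not adjusted. The 13 lines with index numbers alone, taken over both sets, gave r = -0.23. No correlation was computed within the 5 and 4 numbered lines with other index styles. With all deposited peaks r turned to 0.43 and with the stricter q-value to 0.51 (permutation p = 0.0475 and 0.0147), settings in which the levels were not held at equal peak numbers. Spearman's rho in these settings was 0.21 and 0.31 (permutation p = 0.349 and 0.166).

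**Figure D3:**
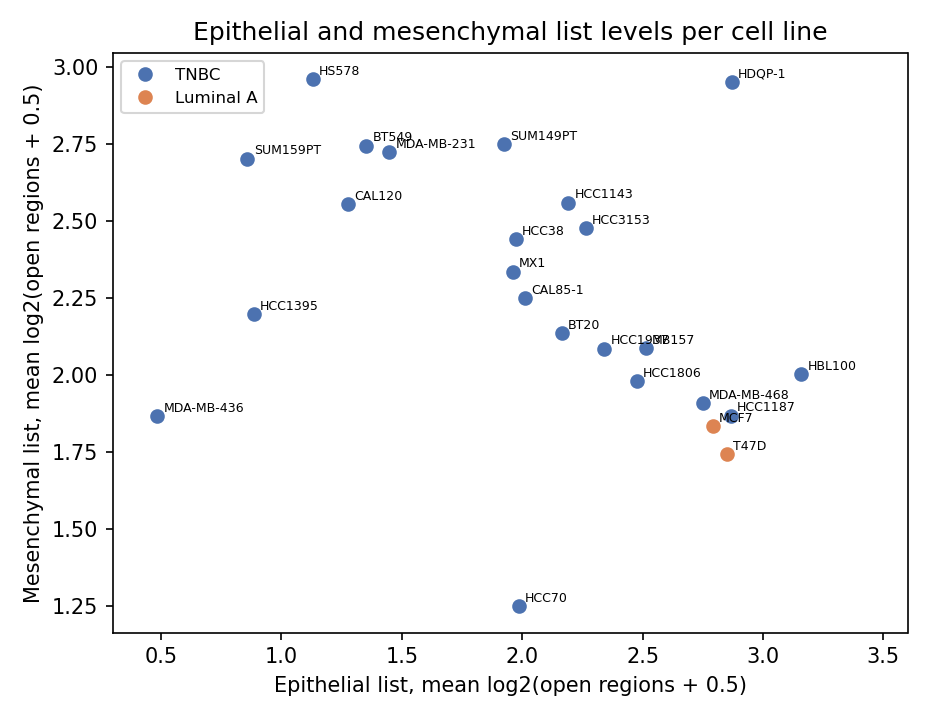
Level of the epithelial list (x axis) against that of the mesenchymal list (y axis), each the mean over genes of log2(open regions + 0.5) at equal numbers of top peaks. Each point is a cell line, blue for TNBC and orange for Luminal A, and r over the 22 TNBC lines is -0.26.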

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

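The test of a mislabelled library, both tests of wide peaks and the overlap of the wide peaks of SUM149PT replicate 2 with other lines were chosen after the results were seen. Peak width is used in no comparison of the report, and 12 libraries held more than 3 peaks over 20 kb, the upper limit on the expected number where 0 are observed, while 31 libraries held none. The unnumbered MDA468 library had 17, MDA-MB-468 replicates 1 and 2 had 17 and 18, and MCF7 had 21. HCC1143 replicates 1 and 2 had 13 and 4, HCC1937 replicates 1 and 2 had 6 and 15, and MX1 replicate 2 had 4. SUM159PT replicates 1 and 2 had 25 and 22, and the library labelled SUM149PT replicate 2 had 29.

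The wide peaks stood at a few loci per line. In MDA-MB-468, 51 lay at chr7:54442794-55652975 around EGFR, a growth factor receptor gene, the widest at 127.6 kb. In SUM159PT, 36 lay at chr8:126923506-128207842 around the oncogene MYC and 7 at chr5:2650135-2768502 by IRX2. In HCC1143, 9 lay at chr11:69280017-69676872 around the cyclin gene CCND1, in MCF7, 8 lay at chr20:53610589-53955887 around BCAS1, and in HCC1937, 21 lay at chr8:141353500-144531256. HCC1937, MX1 and MDA-MB-436 shared the end of chromosome 8 more widely, with 20.1%, 32.2% and 38.9% of libraries of other lines over their wide peaks.

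Leaving out SUM149PT replicate 2, and MCF7, whose single library allows no such test, 98.0% of 147 wide peaks lay over a peak over 5 kb in every other library of their line, against 2.04% in the median library of another line (mean 5.93%), which argues against peak calling in a single library. A candidate explanation is a gain in copy number, which would raise the signal over a whole locus in each library of a line, and the recurrence fits it. Broad open chromatin particular to a line, and the authors' merging of peaks, would recur in the same way and stay open. DNA copy number was not analysed here, so these were not told apart.

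The library labelled SUM149PT replicate 2 had a similarity of at least 0.549 to both SUM159PT libraries and of 0.344 to SUM149PT replicate 1. The values to SUM159PT lay within the range of other same-line pairs (from 0.431) but below the SUM159PT pair itself (0.743). An unnumbered pair of different lines matched them (0.551), in a set where different lines are closer (median 0.398 against 0.302 among numbered libraries). Among numbered libraries labelled as different lines, the highest value, 0.550, was that of this library with SUM159PT replicate 2. There were 26826 regions open in SUM149PT replicate 1 and SUM149 and in neither SUM159PT library. An even mixture of the lines would open many of these, but this library had 3.39% of them open, below libraries of other lines (8.91% to 69.1%). A low peak number is also argued against, since at 20000 top peaks it was still nearest to SUM159PT, at 0.570 against 0.283 for SUM149PT replicate 1. All 29 of its wide peaks lay over a peak over 5 kb in both SUM159PT libraries and 0 over one in another SUM149 library. Of 32627 regions open in both SUM159PT libraries and in neither other SUM149 library, 39.4% were open in it. A library of another line reached up to 44.4% (median 20.4%). Of 2619 regions open in both SUM159PT libraries and in no library of another line, 25.2% were open in it, against 0.917% of 545 regions defined likewise for SUM149. Libraries of other lines hold none of these by definition. A mislabelled library may account for this, which these values leave as a hypothesis.

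For the luminal list the chief technical concern was the set, since both Luminal A lines are unnumbered. The 5 lines with both kinds of library were compared without the library labelled SUM149PT replicate 2. In them the list relative to all genes was 0.10 ± 0.16 (SD) higher in the unnumbered library. It ran from -0.09 in HCC1806 to 0.30 in SUM149PT. The mean was 8.01% of the difference between subtypes over all libraries, which argues against the set as the whole cause. Of 100 splits of the lines into 2 and 22, 1, the real one, gave a camera p as small. At the preset correlation it was 3.23e-09, against 7.45e-06 for the lowest other split. The lowest other split, MDA-MB-231 with T47D, held a Luminal A line, as did the next lowest, SUM149PT with T47D. Each drawn split of TNBC lines alone gave a larger value than these. The rank of the real split argues against an arbitrary pair of lines, but chance is not excluded, since 100 of the 276 pairs were drawn. The splits also ignored the set. Within unnumbered libraries alone, the list levels gave an exact permutation p of 0.0222 (adjusted 0.0622). An oestrogen receptor programme in the Luminal A lines could underlie the pattern, as a hypothesis on 2 lines, and other technical differences between lines were not tested.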

How the results depend on the processing

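The tests by line block and by weight, without peaks over 5 kb, by nearest gene end, without SUM149PT replicate 2, and the correlations within sets were chosen after the data were seen. Between lines, the count moved from 90.6% to 94.4% of genes over all settings, from 15099 to 15541 with 1 library left out, and to 15398 with the replicate block, and the 57 named genes passed in each of the 49 settings in which they were tested, which was fewer for CD33, CD79A, CD4, KRT23, SOX10, CHMP2A and OAS1. Deviations of replicate 1 had a median correlation between lines of -0.00113 over 171 pairs (from -0.506 to 0.375, 21.6% of pairs over 0.1). This shows no pairing by replicate number common to all lines, and does not exclude it for some. The difference in peak number was 67925 and passed with the stricter q-value. With equal top peaks the difference in gene-end share turned to 1.05 by subtype and 0.049 between unnumbered and numbered libraries. Regions open in both Luminal A lines only numbered 2474 with equal top peaks, 10507 in unnumbered libraries and 11109 when open in every library of a line, a rule that favours lines with 1 library. The correlation of the epithelial and mesenchymal lists turned to 0.43 with all peaks and 0.51 with the stricter q-value (permutation p = 0.0475 and 0.0147). In unnumbered libraries r was -0.69 (exact permutation p = 0.00742, not adjusted), while the exact permutation p of rho was 0.0576. The values under 0.05 thus lay in both directions. Genes past the threshold by subtype, 0 in the report, were 39 with equal top peaks (17 higher, 22 lower), 9 with the stricter q-value, 6 with the region's centre covered, 3 within 10 kb, 59 with no filter (52 higher, 7 lower), 2 with names apart and 3 with the line as a block, and from 0 to 1 with a Luminal A line left out. Lists past camera were 5 with the stricter q-value and 5 in unnumbered libraries, and 1 in each with an estimated correlation. KRT5 by subtype turned to -0.34 in unnumbered libraries, and ZEB1 to 0.13 with equal top peaks and 0.19 with no covariate. TP63 by subtype turned to 0.61 with no covariate, 0.077 scaled by peak number and 0.14 with the line as a block, and ran from -0.30 to 0.14 with a Luminal A line left out, and VIM by subtype from -1.05 to 0.00728. The median over all genes moved from 0.24 to 0.73 with no covariate and -0.01 in unnumbered libraries. A line left alone in its group was assumed to vary like the others. Apart from the fewer lines in unnumbered and left-out settings, the cause was not tested. The luminal list passed camera in 16 of 16 settings (adjusted p from 1.28e-10 to 3.95e-05), the mesenchymal in 16 and the basal in 14. With an estimated correlation these were 13 (highest adjusted p = 0.494), 0 and 0. The motif alternatives, and those that needed start sites or summits, were not run. Read depth is unknown, so its effect could not be measured.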

Other observations

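The list levels per line, the pairs of lists, the regions by gene and list, and the count of genes over splits were tests chosen after the results were seen. GREB1, an oestrogen-induced gene, lay near 30 of the regions open in both Luminal A lines only, against at most 3 for any other pair of lines. DSCAM lay near 23, ESR1 and GATA3 near 9 each, and the luminal keratin gene KRT18 near 6, against at most 3, 3, 2 and 0. PREX1 had 16, but another pair had 49. Of 5667 such regions near a gene, 91 lay near luminal list genes (1.61%, against 0.245% of all regions), which did not pass over pairs of lines (exact permutation p = 0.0507, adjusted 0.507), and no other list did. Conversely, 608 regions open in at least 20 TNBC lines were closed in both Luminal A lines, a count that 25 of 276 pairs reached, the Luminal A pair included (exact permutation p = 0.0906).

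Across 22 TNBC lines at equal top peaks, 10 of the 15 pairs of 6 lists were related after adjustment. Basal and luminal progenitor levels had r = 0.89 (rho 0.93), basal and epithelial 0.87 (0.80), luminal and luminal progenitor 0.86 (0.85), and luminal and basal 0.82 (0.78), with a permutation p of 1e-05 for each r, the smallest possible, and an adjusted p of 3.75e-05. Without the lines farthest on the first list of each pair, these were 0.84, 0.81, 0.83 and 0.73. Within the 10 numbered lines with index numbers they were 0.74, 0.50, 0.67 and 0.44, and within the 8 unnumbered TNBC lines 0.85, 0.89, 0.65 and 0.54, without a test. The pooled relations of the AP-1 and YAP/TEAD list with basal (0.73), luminal (0.72) and luminal progenitor levels (0.76) were smaller within these sets, also without a test, where r was 0.085, 0.17 and 0.31 in the numbered lines and 0.43, -0.0088 and -0.0089 in the unnumbered. The epithelial and AP-1 lists (0.51, adjusted p = 0.0232) turned to -0.45 in the numbered lines and stood at 0.073 in the unnumbered. The epithelial list with luminal (0.64) and luminal progenitor levels (0.67) stood at 0.021 and 0.017 in the numbered lines and at 0.73 and 0.90 in the unnumbered. The mesenchymal list was related to none when pooled (adjusted p from 0.107 to 0.944), and its r with luminal progenitor levels was 0.57 in the numbered and -0.82 in the unnumbered lines. The lists share 0 genes, and general openness of a line was not removed.

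By list level relative to all genes, the mesenchymal list was lower in the Luminal A lines at equal top peaks, at -0.28 ± 0.06 against 0.61 ± 0.40 (SD), below 22 of 22 TNBC lines (exact permutation p = 0.00362, adjusted 0.0254). Of the 6 settings it passed adjustment there and without SUM149PT replicate 2, and with all peaks the exact permutation p was 0.0471 and the adjusted p 0.220. In the unnumbered libraries it was below 7 of 8 TNBC lines (exact permutation p = 0.133, adjusted 0.233), and for the list alone the exact permutation p was 0.0978. The luminal list passed in the same settings and stood at adjusted p = 0.0507 for the list alone, with all peaks and with the stricter q-value. For camera, 2 of 100 splits gave a p as small for the basal list and 2 for the mesenchymal list, the real one included, with lower p in another split (1.0e-05 and 2.70e-06). The other split for the basal list, MDA-MB-231 with T47D, held a Luminal A line, and that for the mesenchymal list, HS578 with SUM159PT, did not. For the count of genes by subtype, the real 0 means that 100 of 100 splits must give as many, so this comparison says nothing about chance, and 67 of them also gave 0. BT20 with HCC1937 gave the highest count of these splits, 1367, which points to a structure of the samples, technical or biological, whose cause was not tested.

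Windows of 250 kb that usually hold peaks were tested at 4472 positions in each line, and 446 combinations of line and window, over 20 lines, held no peak, some windows in several lines, with 103 in MDA-MB-436, 95 in HCC70 and 86 in HCC1395. The library labelled SUM149PT replicate 2 was left out here. Their number had a Spearman's rho of -0.36 with the peak number of the line, and 23.8% adjoined another, both between the bounds set beforehand. The window of CDKN2A was empty in MDA-MB-231 and SUM149PT, and that of CDKN2B in HCC38 as well.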
